A study of Drosophila melanogaster with 6 samples.

How the data were processed

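The samples were total RNA from dissected proboscises of male Drosophila melanogaster, 3 poxn70 homozygous and 3 poxn70 heterozygous biological replicates, per the labels. RNA was extracted with Trizol, and about 50 ng per sample was amplified in 2 rounds into biotinylated cRNA for a single-colour Affymetrix array, per the labels' protocols. The deposited log2 values are GCRMA values, per the submitters' processing notes. GCRMA corrects the background of each probe from its sequence, normalizes between arrays and gives 1 value per probe set. Its version is not given in the sources used here, and the log2 scale was read from the range of the values (1.57 to 16.02). GCRMA pulls probe sets without signal to a narrow band of low values, so small differences among them carry little spread and little meaning. Of the probe sets tested, 48.2% had all 6 values under 3, and this background limit was chosen after seeing the values. Detection calls and scanner files were not used here, so signal over background is known only from that band.

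The table held 18952 probe sets, of which 183 were array controls and were left out of the tests. Gene names came from the platform annotation. Of the 18769 probe sets tested, 13647 had 1 gene, 402 had several and 4720 had none, and no gene was named from a probe set with several. Symbols were looked up through the Entrez identifier in a RefSeq gene table (assembly Release 6 plus ISO1 MT), which matched 13544 of the 1-gene probe sets and left 103 with their annotated symbol. The deposited values name no genome build, so the gene table served for names, chromosome arms and gene order only, and no coordinates are given. Genes with several probe sets (1094 of 11983) were represented by the probe set with the highest mean over the 6 arrays.

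Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), homozygous minus heterozygous, over all probe sets that were not controls, with Benjamini-Hochberg adjustment and a threshold of 0.05. Where all 3 values of 1 group lay under the background limit, the change is given as a bound (at least N-fold), computed from the mean of the brighter group against 3. Where both groups lay under it, no fold is given. The genes named in the text were Poxn, then the 12 largest decreases and 8 largest increases among genes past the threshold with groups that did not overlap. To these were added up to 4 members of each fixed list with the smallest unadjusted p (6 for sugar, bitter and maxillary palp receptors and pickpocket channels). Genes outside this rule are said to be so where they are named, or complete a count. Per array, exact permutation tests and correlations described the controls and the similarity of replicates.

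The 32 gene lists were fixed before the data were examined. They covered gustatory receptors (all, sugar and bitter), ionotropic receptors, pickpocket channels, odorant-binding proteins, odorant receptors (all and maxillary palp), CheA and CheB proteins, TRP channels, mechanosensory transduction, cilium and intraflagellar transport, neuronal and synaptic genes, and sense organ development. They also covered glia, muscle, fat body, hemocytes, photoreceptors, testis, accessory gland, digestive enzymes, immune-induced peptides, cytochrome P450 enzymes, glutathione S-transferases, UDP-glycosyltransferases, heat shock proteins, oxidative phosphorylation, ribosomal proteins, cuticle proteins, circadian clock and neuropeptides. Each list was tested with camera (preset correlation 0.01, with an intensity trend), adjusted over the 32 lists, with an estimated correlation, fry and Fisher's exact test as further tests. Of the 18 lists that camera called, 2 (bitter gustatory receptors, and cilium and intraflagellar transport) were called with an estimated correlation. Counts of members are given over all probe sets tested and adjusted over the list alone. The sugar and bitter lists lie within the gustatory receptors, and the maxillary palp list within the odorant receptors. The mechanosensory list shares 3 genes with the cilium list and 3 with the TRP channels, so these lists are not separate. TRP channels share 2 genes with photoreceptors, odorant-binding proteins 1 with fat body, and clock genes 1 with neuropeptides.

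The labels number the replicates of both genotypes from 1 to 3 and do not say that a number marks a shared day or batch. Deviations from the group means of same-numbered arrays correlated at 0.372, 0.288 and 0.142 over probe sets for numbers 1, 2 and 3, so the numbers were taken to pair the arrays, from the data and not from the labels. Homozygous replicate 3 correlated higher with heterozygous replicate 2 (0.275) than with its own number. Within each genotype, number 1 deviated against numbers 2 and 3 (-0.79 and -0.82 in homozygotes, -0.61 and -0.74 in heterozygotes). The 3 correlations are therefore not independent, and the pairing is uncertain. The hybridization controls added to the cRNA averaged 10.39 and 10.37 on both arrays numbered 1 and 9.43 to 9.59 on the other 4. The fit without a block was the one fixed before the data were examined, and the fit with the replicate number as a block was chosen then as well. Other alternatives were quantile normalization, median centring, other variance moderation, array weights, leaving out dim probe sets, stricter thresholds, and leaving out each array in turn.

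The fit was tested on simulated arrays, drawn from normal distributions with the heterozygous mean and the within-group SD of each probe set. In each of 5 draws, 200 of 18769 probe sets were lowered, all of them bright in heterozygotes (4 or more log2 units above the background limit). It called 19.6% of those lowered 2-fold, 56.4% of those lowered 4-fold, 85.2% of those lowered 16-fold and 92.8% of those lowered 64-fold, over 250 probe sets of each size, with 33 unchanged probe sets called over the 5 draws. Camera called the lowered list in all 5 draws and 0 of 1000 unchanged lists of 20 probe sets, in data simulated without correlation between genes.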

Results

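Gene expression was measured in proboscises, the main taste organ of the fly head, of male Drosophila melanogaster that carried the poxn70 allele on both chromosomes or on one. Pox neuro (Poxn) encodes a paired-domain transcription factor that gives taste bristles their chemosensory identity, and bristles that lack it develop as mechanosensory bristles. The comparison therefore asks which transcripts of the proboscis depend on Poxn, taste neuron transcripts among them. There were 3 biological replicates of each genotype and 1 array per replicate, 6 arrays in all. Males were 8 to 18 days past eclosion, and 164 to 280 proboscises went into each array. All values are log2 GCRMA values, each mean is given with its SD over 3 arrays, and differences are homozygous minus heterozygous. The number of arrays limits the precision, and values under 3 on the log2 scale were treated as background.

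Poxn itself was read near background in both genotypes, at 2.46 ± 0.16 (SD, n = 3) in homozygotes and 2.34 ± 0.04 (SD, n = 3) in heterozygotes. All 6 values lay under the limit of 3, and limma gave an adjusted p of 0.611. The probe set of the gene therefore gave no check of the genotype labels.

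Among probe sets past the adjusted threshold, more fell than rose in homozygous proboscises. Of 18769 probe sets, 59 were lower and 11 higher at an adjusted p under 0.05 (limma), which stood for 53 lower and 9 higher genes when each gene was given 1 probe set. At an unadjusted p under 0.05 the balance was the other way, with 545 lower and 813 higher. With the dimmer 50% of probe sets left out these counts were 519 and 564, so much of that surplus lay among dim probe sets. The largest decrease among called genes was in Cyp6a17, a cytochrome P450, at 2.90 ± 0.49 against 11.85 ± 0.32, with 2 of the 3 homozygous values under the background limit (adjusted p = 0.00397). Osi8, a member of the Osiris family, was at least 86.0-fold lower (heterozygous mean 9.43, all 3 homozygous values under the limit, adjusted p = 0.00499). CG6290 fell from 13.94 to 5.57, CG14518 from 12.07 to 4.72, CG32271 from 12.50 to 5.33 and CG8157 from 13.21 to 6.28. The 12 largest decreases also held NimB2, a Nimrod family gene, at 5.65 against 11.63, and CG14277 at 9.94 against 15.19. They further held the Sox-domain transcription factor D (Dichaete) at 3.24 against 8.41, with 1 homozygous value under the limit. All 70 called probe sets had groups that did not overlap, which fixes the same sign in all 3 same-numbered pairs. Selection by p on these same arrays favours such probe sets, so this is no further support for the calls. Chance gives non-overlap in 10% of probe sets, and 22.9% of all probe sets showed it (841 lower and 3465 higher). The replicate numbers were taken to pair the arrays, which the labels do not state. With the replicate block limma called 0 lower and 0 higher probe sets (smallest adjusted p 0.131), so every single-gene call given here ended under the block. The block also leaves fewer degrees of freedom, so lost power and failed calls cannot be told apart here. At an unadjusted p under 0.05 the block gave 606 lower and 2022 higher, and 610 and 688 with the dimmer 50% of probe sets left out. With the dimmer 50% of probe sets left out as well, an alternative chosen after seeing the data, the block called 74 lower and 18 higher. With the replicate number as a random block, also chosen after seeing the data, 117 were lower and 50 higher, and all 70 calls were kept. The count of calls also moved when 1 array was left out, which lowers the power of the fit as well. In each of these 6 fits all 70 called probe sets, picked from the same arrays, kept their sign and an unadjusted p under 0.05. Without homozygous replicates 1, 2 and 3 in turn, 54, 12 and 6 probe sets were lower and 12, 1 and 2 higher. Without heterozygous replicates 1, 2 and 3, 39, 6 and 14 were lower and 0 were higher each time. Of the 43 called genes named in the text, Cyp6a17, Osi8 and spz5, the last chosen after its values were seen, kept their call in all 6 of those fits, and 10 genes kept it in none.

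**Figure D1:**
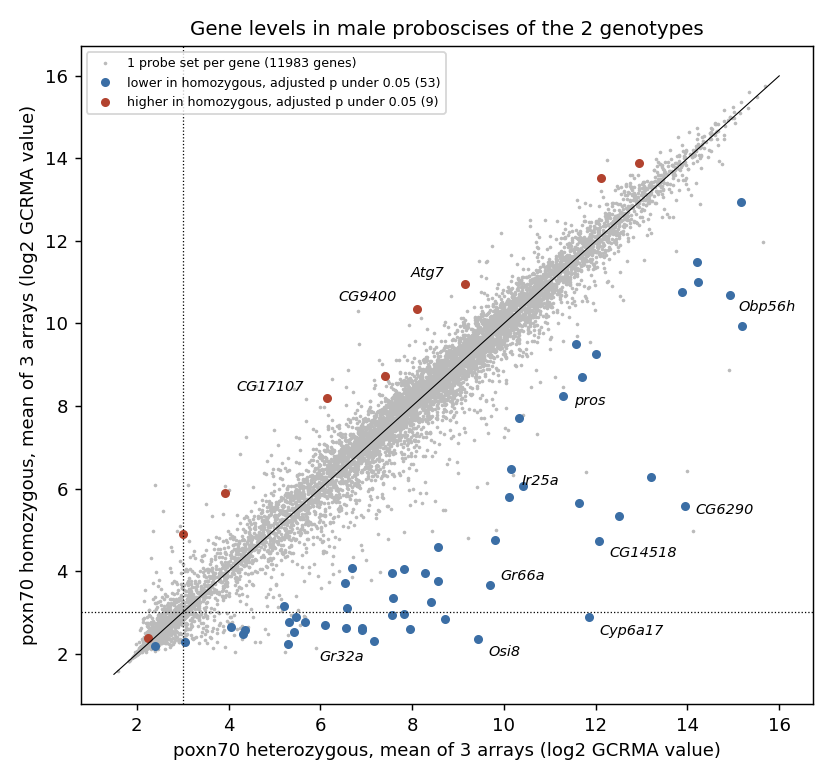
Mean log2 GCRMA value of each gene (1 probe set per gene) over the 3 homozygous arrays against the 3 heterozygous arrays, with the dotted lines at the background limit of 3 and the solid line at equality. The 53 lower genes lie below the line, some with homozygous values under the limit, and the 9 higher genes lie above it by at most 2.25 log2 units (CG9400).

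Bitter taste receptors with signal above background were lower in homozygotes. Of 33 bitter gustatory receptor genes on the array, 16 were above the background limit in at least 1 genotype, and all 16 had lower means in homozygotes with groups that did not overlap. In 12 of the 16 all 3 homozygous values lay under the limit, so the median decrease is a bound, at least 3.82-fold. Over all tests 8 were called lower, and 17 were lower when adjusted over the list alone (limma), 15 of them above the limit. Gr66a, a receptor found in nearly all bitter neurons, stood at 3.66 ± 1.05 against 9.69 ± 0.45, with 1 homozygous value under the limit (adjusted p = 0.0381). Gr32a and Gr33a, which also act in the avoidance of male pheromone, were lower as well. Gr32a fell at least 18.0-fold (adjusted p = 0.0176), and Gr33a was at 2.94 ± 0.51 against 7.57 ± 0.20, with 2 of 3 homozygous values under the limit (adjusted p = 0.0192). Gr93a, needed for the taste of caffeine, was at least 4.88-fold lower, Gr47a at least 5.37-fold and Gr22f at least 14.9-fold, each with all 3 homozygous values under the limit. Gr93b, which completes the 8 calls and was chosen after its values were seen, was at least 2.48-fold lower, and Gr98b was under the limit in both genotypes and has no fold. The list was lower as a set (camera adjusted p = 9.91e-21) and remained so with an estimated correlation (adjusted p = 0.0223). The 5 sugar receptors with a 1-gene probe set gave 0 calls over all tests and 2 lower when adjusted over the list alone, which were Gr64f and Gr64a. Some probe sets of the Gr64 cluster match several genes and were left out, so the sugar list is incomplete. Gr64f was at 3.73 ± 0.76 against 6.20 ± 0.29 (limma adjusted p = 0.192), and Gr64a was at least 2.45-fold lower (adjusted p = 0.138). Gr5a, a receptor for trehalose, was at 2.99 ± 0.25 against 3.79 ± 0.56, with 2 homozygous values under the limit. Gr61a was at 2.80 ± 0.02 against 3.15 ± 0.25, with all 3 under it, and both had an adjusted p of 0.611. Gr43a, a fructose receptor, was under the limit in both genotypes. The sugar list was lower by camera (adjusted p = 0.000616), but not with an estimated correlation (adjusted p = 0.179). Over all 56 gustatory receptors on the array, 20 were above the limit, 8 were called lower, and 19 were lower when adjusted over the list alone, 17 of them above the limit. None was higher in either count, and with the replicate block 19 were again lower when adjusted over the list alone. The camera adjusted p of this family was 2.09e-15, and it was lost with an estimated correlation (adjusted p = 0.103). By Fisher's exact test, two-sided, called lower genes were more frequent in the family than among other genes (adjusted p = 1.63e-09).

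**Figure D2:**
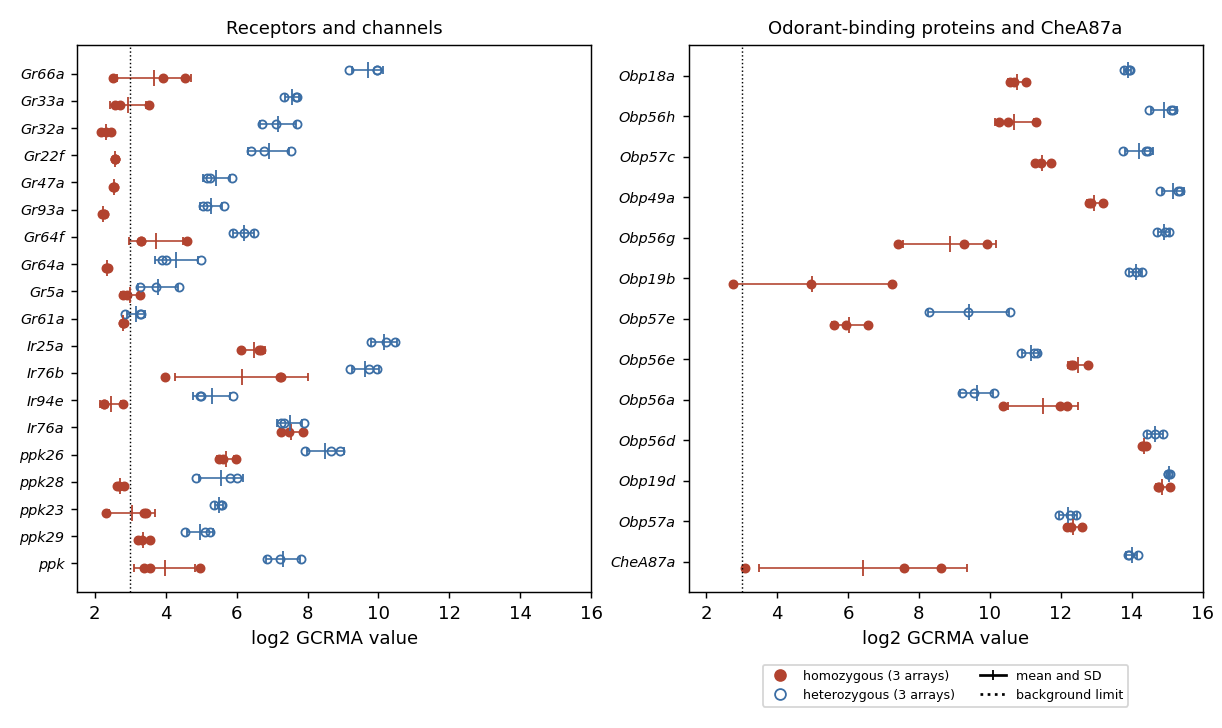
Log2 GCRMA values of receptor, channel, odorant-binding protein and CheA87a genes on each array, filled for homozygous and open for heterozygous proboscises (3 arrays each), with bars at the mean ± SD and a dotted line at the background limit of 3. The homozygous values of Gr66a, Gr33a, Gr32a and Ir25a all lie below the heterozygous ones, those of Ir76a overlap, and Obp56e lies higher in homozygotes.

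Single ionotropic receptors and pickpocket channels were lower, while camera called neither family as a set. Of 53 ionotropic receptors on the array, 8 were above the limit, and 7 of these had lower homozygous values in all 3 pairs. Ir25a, a co-receptor shared by many chemosensory neurons, fell 12.7-fold, from 10.16 ± 0.35 to 6.49 ± 0.31 (limma adjusted p = 0.0176), the only call of the family over all tests. Adjusted over the list alone 4 were lower, namely Ir25a, Ir94e, Ir56d and Ir21a. Ir94e was at least 4.90-fold lower (adjusted p over all tests 0.0528). Ir76b, another co-receptor, was at 6.14 ± 1.88 against 9.63 ± 0.39 and passed neither test (adjusted p = 0.484). Ir76a was at 7.54 ± 0.32 against 7.50 ± 0.35 (adjusted p = 0.932). These last 2 genes were chosen after their values were seen. The family as a set was not called by camera (adjusted p = 0.361), with most of its members at background, but fry called it lower (adjusted p = 0.0318). Camera also called it lower with the dimmer 50% of probe sets left out (1.96e-09). Of 28 pickpocket sodium channel genes, 6 were above the limit and all 6 were lower in homozygotes without overlap, with a median decrease of at least 5.26-fold. None passed over all tests, and 5 were lower when adjusted over the list alone (limma). They were ppk28, the channel for the taste of water (at least 5.92-fold), ppk23 (3.05 ± 0.64 against 5.50 ± 0.12, with 1 homozygous value under the limit) and ppk29 (-1.60), which detect pheromones, and ppk (-3.33) and ppk26 (-2.81), known from nociceptive neurons. Their smallest adjusted p over all tests was 0.0519, for ppk26. Without both arrays numbered 1, as an alternative chosen after seeing the data, 3 were lower. Camera did not call the list (adjusted p = 0.262), but called it lower without heterozygous replicate 1 (0.0422) and with the dimmer 50% of probe sets left out (1.96e-09).

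Odorant-binding proteins, secreted carriers made by support cells of chemosensory hairs, did not move together. Of 48 on the array, 25 were above the limit, and 4 were called lower over all tests. Obp18a was 8.72-fold lower (13.88 ± 0.09 to 10.76 ± 0.23, limma adjusted p = 0.0104) and Obp56h 18.7-fold (14.92 ± 0.37 to 10.69 ± 0.55, adjusted p = 0.0263). Obp57c was 6.59-fold lower, and Obp49a, which lets bitter compounds suppress sweet taste, was 4.63-fold lower. Adjusted over the list alone 7 were lower and 1 was higher (8 and 0 with the replicate block). Of the others in these counts, chosen here after their values were seen, Obp19b stood at 4.98 ± 2.23 against 14.11 ± 0.18, with 1 homozygous value under the limit (adjusted p over all tests 0.0663) and Obp56g at 8.87 ± 1.31 against 14.91 ± 0.16 (0.0519). The seventh was Obp57e (-3.37, 0.213), and the higher one was Obp56e, at 12.47 ± 0.27 against 11.15 ± 0.25 (0.119). Obp19d, at 14.86 ± 0.18 against 15.04 ± 0.03, and Obp57a, at 12.36 ± 0.22 against 12.21 ± 0.25, also chosen after their values were seen, passed neither test. Without overlap, 9 members were lower and 6 higher. The family was not called by camera (adjusted p = 0.125; 0.00545 with the dimmer 50% of probe sets left out), fry called it lower (0.0312), and called lower genes were enriched in it by Fisher's exact test, two-sided (adjusted p = 0.000613). Of 12 CheA and CheB genes, 3 were above the limit and all 3 had lower homozygous means. CheA87a was at 6.42 ± 2.94 against 14.00 ± 0.16 (adjusted p = 0.234). None of the 3 was called over all tests, 1 was lower when adjusted over the list alone (0 with the replicate block), and camera did not call the list (adjusted p = 0.126). It called it lower without heterozygous replicate 2 (0.00406) and with the dimmer 50% of probe sets left out (0.000954).

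Cilium genes were lower as a set, and nompA and pros fell as single genes. nompA, which encodes a matrix protein that ties the sensory dendrite to the cuticle, fell 20.1-fold, from 8.28 ± 0.68 to 3.95 ± 0.10 (limma adjusted p = 0.0324). pros (prospero), a homeodomain factor of sense organ lineages, fell 8.30-fold, from 11.30 ± 0.25 to 8.24 ± 0.34 (adjusted p = 0.0207). Each was the only call of its list over all tests. The mechanosensory list of 9 genes had 2 lower when adjusted over the list alone (1 with the replicate block), and the sense organ development list of 12 had 1. Camera called both lower (adjusted p = 0.0387 and 0.0455), but neither with an estimated correlation (adjusted p = 0.454 and 0.344) nor with the replicate block (0.105 for both). The mechanosensory call also ended without homozygous replicate 1 (0.299) or 3 (0.120). The sense organ call ended without homozygous replicate 2 (0.0975) or 3 (0.138) and without heterozygous replicate 1 (0.131) or 2 (0.0554). Of 29 cilium and intraflagellar transport genes, 22 were above the limit, with a median difference of -0.62 (-0.52 with values under the limit set to 3). Of these 22, 18 were lower in all 3 same-numbered pairs and 12 were lower without overlap. The list was lower by camera (adjusted p = 1.2e-09) and remained so with an estimated correlation (adjusted p = 0.0460). None of its members passed over all tests, and 4 were lower when adjusted over the list alone, namely BBS9 (-2.02), BBS4 (-1.54), ktub (-1.23) and Oseg2 (-1.05). With the replicate block 0 passed over the list alone. Neuronal and synaptic genes, 16 of 19 above the limit, had a median difference of -0.31. Appl, a neuronal membrane protein, was the 1 gene lower when adjusted over the list alone (-1.16, adjusted p over all tests 0.158), and elav, chosen outside the naming rule, was at 7.65 ± 1.19 against 8.82 ± 0.30. Camera called this list lower (adjusted p = 3.31e-05), but not with an estimated correlation (adjusted p = 0.179). Appl did not pass over the list alone with the replicate block, and homozygous replicate 1 had a list median of 0.04, against -0.42 and -0.58 in replicates 2 and 3.

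Among called genes, increases were fewer and smaller than decreases. The 8 largest were CG9400 at 10.36 ± 0.26 against 8.11 ± 0.24 (4.75-fold, limma adjusted p = 0.0307), CG17107 (4.13-fold), CG2070 (3.98-fold), CG10936 (4.89 ± 0.33 against 3.01 ± 0.07, with 2 heterozygous values under the limit), Atg7 (3.50-fold), CG15282 (2.64-fold), CG8858 (2.50-fold) and CG34165 (1.93-fold). Among the fits that left out 1 array, CG17107 and CG10936 kept their call in 1 each, and the others of these 8 kept it in none. Atg7 encodes an enzyme of autophagosome formation. Immune-induced peptides had higher homozygous means, unequally between arrays. All 11 above the limit, of 17 on the array, had higher homozygous means, 9 without overlap, with a median difference of 1.30. The list medians were 1.63 and 0.59 in homozygous replicates 2 and 3, and the median was highest in homozygous replicate 1, the array that stood apart from the others. PGRP-SB1 (3.84-fold), Mtk (3.02-fold), Def (2.15-fold) and BomS2 (1.49-fold) were higher when adjusted over the list alone, and 0 were called over all tests by limma, where the adjusted p values ran from 0.324 to 0.438. Camera called the list higher (adjusted p = 1.3e-05), but not with an estimated correlation (adjusted p = 0.286). Blood cell genes shifted the same way, with a median difference of 0.44 over 11 of 13 genes. PPO1, a prophenoloxidase of crystal cells, at 10.74 ± 0.20 against 9.57 ± 0.12, Hml (1.81-fold) and Sr-CI (2.21-fold) were higher when adjusted over the list alone, and 0 were called over all tests. The camera adjusted p of 0.0192 became 0.286 with an estimated correlation and 0.0588 with the replicate block. It also missed the threshold without homozygous replicate 2 (0.0610), without heterozygous replicate 1 (0.0797) and without both arrays numbered 1 (0.132).

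Single cytochrome P450 genes fell. Of 80 cytochrome P450 genes, 66 were above the limit, and 4 were called lower over all tests, against 0 higher. Besides Cyp6a17 they were Cyp6a2, at 2.83 ± 0.45 against 8.71 ± 0.80 with 2 homozygous values under the limit, Cyp308a1, at least 30.9-fold lower, and Cyp6a20, known from work on male aggression, 6.71-fold lower. Adjusted over the list alone 10 were lower and 2 higher. Camera called the family lower (adjusted p = 3.31e-05), but not with an estimated correlation (adjusted p = 0.286), and called lower genes were enriched in it by Fisher's exact test, two-sided (adjusted p = 0.00337). Glutathione S-transferases, 29 of 34 above the limit, were higher by camera (median difference 0.41, adjusted p = 0.00671; 0.286 with an estimated correlation), with 0 members past either count and GstE2 at 8.26 ± 0.03 against 7.29 ± 0.32. Of UDP-glycosyltransferases, 15 of 35 above the limit, 1 was higher when adjusted over the list alone, Ugt36D1 (2.11-fold), and camera gave an adjusted p of 0.0297 (0.344 with an estimated correlation). That call ended without homozygous replicate 3 (0.129) and without heterozygous replicate 1 (0.0695) or 2 (0.0628). Heat shock genes were lower by camera (adjusted p = 0.00615; 0.179 with an estimated correlation), with Hsp26 at 13.12 ± 0.22 against 14.08 ± 0.18 the 1 gene of 13 lower when adjusted over the list alone (0 with the replicate block).

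Genes of the other tissues of a proboscis gave few differences. Muscle (22 genes above the limit, median difference -0.07), fat body (10 genes, 0.05) and glia (8 genes, 0.06) had 0 members past either limma count, and camera called none of these lists (adjusted p = 0.301, 0.935 and 0.500). The glial list had a positive median and a camera direction of lower, as did ribosomal protein genes. The glial marker repo differed by -0.40 (limma adjusted p = 0.611), and with the replicate block 1 glial gene was higher when adjusted over the list alone. Ribosomal protein (adjusted p = 0.542), circadian clock (0.301), neuropeptide (0.866), TRP channel (0.726) and testis genes (0.729) were not called either. Oxidative phosphorylation genes (median difference 0.16, camera adjusted p = 0.0192; 0.454 with an estimated correlation) and cuticle protein genes (0.25, 0.0387; 0.609) were called higher with 0 members past either count. Both calls ended without homozygous replicate 2 (0.0610 for each) or 3 (0.0565 and 0.120), and that of cuticle genes also without heterozygous replicate 1 (0.128). Odorant receptors were mostly at background, as only Orco (4.45 ± 0.93 against 6.05 ± 0.59) and Or1a (9.91 ± 0.47 against 8.78 ± 0.74) of 57 were above the limit. Neither passed a test (adjusted p = 0.611). The camera call of that list (higher, adjusted p = 0.00433, and 0.634 with an estimated correlation) stood beside a list median of 0.004. It was lost with dim probe sets left out, so it rested on members at background. It missed the threshold without homozygous replicate 2 (0.0652) or heterozygous replicate 1 (0.0797), and the direction turned with quantile normalization (0.752). Of 8 receptors of the maxillary palp, a nearby olfactory organ, Orco alone was above the limit, and the list was not called (0.782).

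Some arrays carried transcripts that followed neither genotype. Male accessory gland genes were high in heterozygous replicate 1 alone, where the median of 6 genes lay 2.14 above the heterozygous mean, against -1.14 to -0.98 in the other 5 arrays. The camera call of that list (lower, adjusted p = 0.0179; 0.634 with an estimated correlation) turned to higher without this array (0.0834), and it also ended without homozygous replicate 2 (0.0514) or 3 (0.0729). Photoreceptor genes were low in homozygous replicate 3 (-1.95) and heterozygous replicate 1 (-1.25). Their camera call (lower, adjusted p = 0.00696; 0.454 with an estimated correlation) ended without homozygous replicate 3 (0.492). Digestive enzyme genes ranged from -2.55 in homozygous replicate 3 to 0.98 in homozygous replicate 1, and the list was not called (adjusted p = 0.575). Homozygous replicate 1 had a mean correlation of 0.971 with the other arrays, which ranged from 0.984 to 0.987. Its control transcripts were also short of upstream signal. The 5′ probe set of GAPDH minus its 3′ probe set gave -10.81 log2 units there, against -5.69 to -4.42 on the other 5 arrays.

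**Figure D3:**
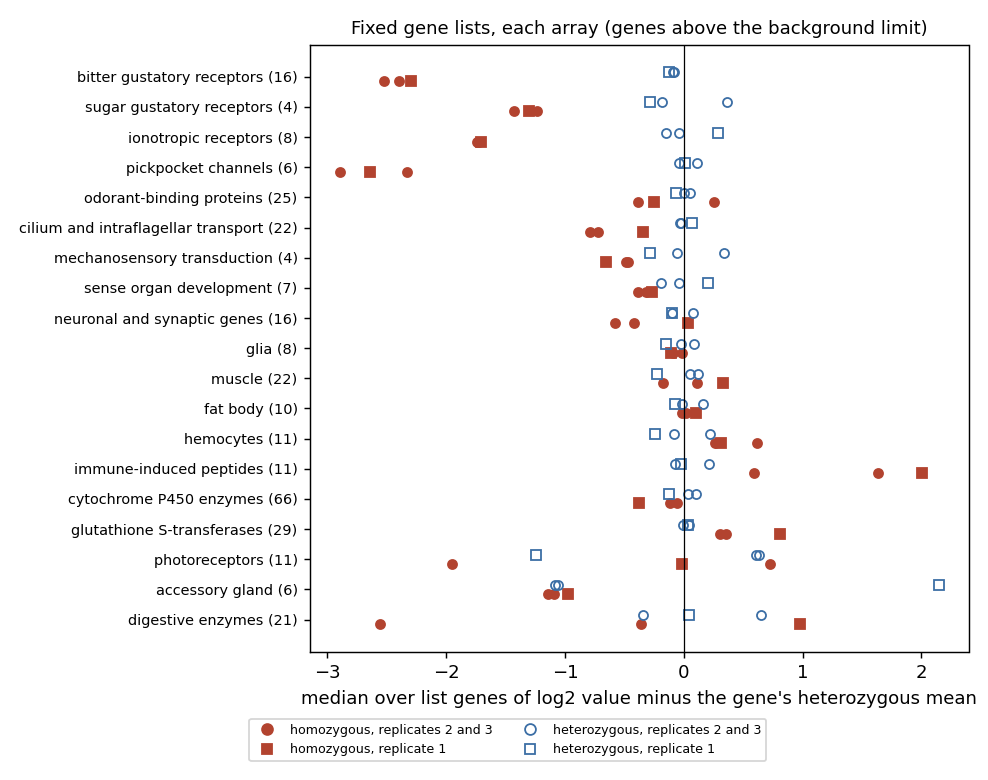
Median, over the genes of each fixed list above the background limit (number in brackets), of the log2 value minus the heterozygous mean of the gene, for each array; filled symbols are homozygous, open symbols heterozygous, squares replicate 1 and circles replicates 2 and 3. All 3 homozygous arrays lie between -2.53 and -2.30 for bitter gustatory receptors, while the accessory gland list is high in 1 heterozygous array only.

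Poxn lies on the right arm of chromosome 2 (2R), and the 2 genotypes differ in 1 copy of that chromosome, so the place of the differing genes was compared between arms. Of genes past the adjusted p threshold (limma), 19 lay on 2R, 14 on 2L, 13 on 3R, 8 on 3L and 7 on X. The share on 2R was 0.783% of its genes against 0.447% on the other arms, an odds ratio of 1.76 that did not pass (Fisher's exact test, two-sided, p = 0.0546, adjusted p = 0.273). At an unadjusted p under 0.05, 5.35% of 2R genes were lower against 3.45% elsewhere (odds ratio 1.58, adjusted p = 0.000156), and 6.10% were higher against 4.51% (odds ratio 1.37, adjusted p = 0.00855). Genes on an arm are not independent replicates, so these p-values describe the arrays at hand.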

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

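Fits that leave out the arrays numbered 1, that treat the replicate number as a random block or number 1 as a batch, and that combine leaving out dim probe sets with a block or with weights were chosen after seeing the data. The count of differing probe sets (59 lower and 11 higher) moved with most settings. It was 117 and 35 after median centring, 123 and 33 with the lower 50% of probe sets left out, and 35 and 13 with eBayes without the trend. It was 88 and 29 with a smaller share of dim probe sets left out, and 4 and 0 at an adjusted p under 0.01. With the replicate block it was 0 and 0, with the block and the lower 50% left out 74 and 18, with a random block 117 and 50, and with number 1 against 2 and 3 as a block 35 and 6. Without both arrays numbered 1 it was 9 and 0. Leaving out 1 array gave 6 to 54 lower and 0 to 12 higher. Array weights gave 1689 and 6520 without converging, with weights from 0.0759 to 72.2, and 565 and 483 after the lower 50% was left out. The cause of these shifts was not tested. All 70 called probe sets kept their sign and an unadjusted p under 0.05 in each setting that tested them. They were picked from these same arrays, so this is no independent support.

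Poxn was called in no setting. Of 85 genes in the text, 2 changed sign, both without a call. They were Ir76a without homozygous replicate 1 (-0.13) and without heterozygous replicates 2 (-0.04) and 3 (-0.08), against 0.24 without heterozygous replicate 1, and Obp57a without both arrays numbered 1 (-0.11). Of the 43 called genes in the text, 39 were called after quantile normalization, 24 without the trend, 42 with median centring, 43 with robust moderation or array weights, and 0 with the replicate block.

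Of the 18 lists called by camera, an estimated correlation kept 2. Among those lost were gustatory (0.103), sugar receptor (0.179) and neuronal genes (0.179), and hemocyte, immune peptide, cytochrome P450 and glutathione S-transferase genes (0.286 each). Fry kept 12, lost 6 with neuronal genes (0.0888) among them, and gained ionotropic receptors (0.0318) and odorant-binding proteins (0.0312). Quantile normalization kept 15, median centring and the smaller share of dim probe sets left out 16 each, and the lower 50% left out 14, and the losses were among odorant receptor, accessory gland, UDP-glycosyltransferase and cuticle genes. Each of these 4 settings gained the same 4 lists, all lower, which were ionotropic receptors, pickpocket channels, odorant-binding proteins, and CheA and CheB proteins. Without both arrays numbered 1, muscle genes were lower (0.0125). The replicate block kept 15 and lost mechanosensory, sense organ and hemocyte genes (0.0588 for hemocytes), and changed no other list call. Hemocyte genes gave 0.00190 to 0.0797 with 1 array left out and 0.132 without both arrays numbered 1. Accessory gland genes turned to higher without heterozygous replicate 1 (0.0834) and without both arrays numbered 1 (0.139), against 0.000402 to 0.0834 over the fits without 1 array. Odorant receptors turned to lower after quantile normalization (0.752). Lower ionotropic receptors, adjusted over the list alone, were 7 after median centring and with either share of dim probe sets left out, and with the block when the lower 50% was left out. Lower pickpocket channels were 3 without both arrays numbered 1.

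The odds ratio of 2R passed at an unadjusted p under 0.05 (1.49) and with the lower 50% left out (2.02). Others then past the threshold were 2L (1.53), 3L (0.447) and 3R (0.635) with the lower 50% left out, and 3L (0.776) and X (0.747) at an unadjusted p. With the replicate block no gene was called, so arms had no ratio. With the block and the lower 50% left out, the ratio of 2R was 1.56 and passed no more (adjusted p = 0.235), and the same held for the other arms. At the adjusted threshold, the ratio of 2R also passed in no fit that left out 1 array (0.967 to 1.94). The pseudocount alternative was not run, because the deposited values are log2 already. Signal over background limits decreases that end in the background to bounds.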

Other observations

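Further genes outside the fixed lists fell with the taste receptors, and those named here were chosen after their values were seen. spz5, which encodes a Toll-receptor ligand with neurotrophic activity, had the smallest unadjusted p of all genes, at 4.75 ± 0.10 against 9.80 ± 0.22 (limma adjusted p = 0.00397). Transcription factor genes among the decreases were grn, a GATA factor, at 6.07 ± 0.47 against 10.42 ± 0.31, fuss, at least 8.63-fold lower, and Fer1, at 3.11 ± 0.39 against 6.59 ± 0.23, close to the background limit in homozygotes. Other called decreases were Cln3 at 3.35 ± 0.06 against 7.58 ± 0.42, Sgsh at 4.59 ± 0.21 against 8.56 ± 0.37 and Hexo2, 4.18-fold lower. These 3 are known from lysosomal function, and no list of lysosomal genes was tested. Snmp2, of the CD36 family, fell 8.08-fold, from 11.71 ± 0.14 to 8.69 ± 0.46. With the replicate number as a fixed block none of these calls held, and as a random block all of them did.

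The tests of upstream signal, of heterozygous flies, of 2L and of 2R outside the Poxn window were chosen after the result was seen; the others below were fixed first. Other groupings of the 6 arrays gave fewer calls. The genotypes gave 70 called probe sets, and the highest of the other 9 splits gave 0, so 1 of 10 splits reached the real count. The 3 other splits that part all 3 pairs gave 0 as well. For gene lists, the genotypes gave 18 lists called by camera, the highest other split gave 8, and 1 of 10 splits reached the real count. With 10 splits the share cannot fall under 0.1, so chance was neither excluded nor shown. Each other split also mixes the genotypes, so a genotype difference widens its within-group spread and can enter its list tests. Bitter receptors reached a camera adjusted p of 0.000345 in 1 such split. The counts of the other splits therefore do not show what chance alone gives. At an unadjusted p under 0.05 the genotypes gave 1358 probe sets. Homozygous replicate 1 with heterozygous replicates 1 and 2 against the rest gave 3375, and the other 8 splits gave 62 to 638. What sets the largest count was not tested.

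The array of homozygous replicate 1 stood apart from the other 5. Heterozygous flies in that sample are argued against by its bitter receptors, whose median lay at -2.30 against the heterozygous mean, far outside the heterozygous range of -0.12 to -0.08. Loss of upstream transcript sequence may account for it. Control transcripts averaged -7.17 log2 units between middle or 5′ and 3′ probe sets there, against -3.98 to -3.37 on the other arrays. Gut tissue carried into the sample was tested as the whole cause, and of 2458 brighter probe sets that deviated by over 1 log2 unit, 55.5% were lower, which neither needs nor excludes it.

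Genes past an unadjusted p under 0.05 and above the background limit were more frequent on chromosome 2. As a share of the genes above the limit on each arm, they made up 16.1% on 2R and 13.7% on 2L, against 10.7% on 3L, 3R and X. The intervals given here treat genes as independent, which genes on an arm are not, so they describe the arrays at hand. On these arrays the genes of the chemosensory lists lying on 2R do not account for the excess there. The odds ratio of 2R against the other arms was 1.49 (95% interval 1.27 to 1.75) with these genes. It was 1.49 (interval 1.27 to 1.76) with all chemosensory lists left out. Linked sequence near Poxn as the whole cause is argued against, since 2R outside a window of 100 gene ranks on each side of Poxn gave an odds ratio of 1.60 (interval 1.35 to 1.90) against 3L, 3R and X. An added share near Poxn stays open, as genes within the window gave an odds ratio of 1.04 against the rest of 2R, with a wide interval (0.612 to 1.69). A hypothesis is that sequence differences along the whole of chromosome 2, between the poxn70 chromosome and its partner, may add to the differences. Genes on 2L, which does not carry Poxn, gave an odds ratio of 1.33 (interval 1.11 to 1.60) against 3L, 3R and X. With 2R among the compared arms and dim genes kept, the ratio of 2L was 1.11 (Fisher's exact test, two-sided, adjusted p = 0.242). Of the 4 cytochrome P450 genes called lower, 3 (Cyp6a17, Cyp6a2 and Cyp6a20) lie on 2R, and whether they follow Poxn or a linked difference was not tested. The same holds for every other called gene on chromosome 2. Of called higher genes 4 lay on 2R, 3 on 2L, 1 on 3L, 0 on 3R and 1 on X. Of called lower genes 15 lay on 2R, 11 on 2L, 7 on 3L, 13 on 3R and 6 on X. Neither share on 2R passed (Fisher's exact test, two-sided, adjusted p = 0.309 and 0.744).

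The poly-A spike controls differed in mean between the genotypes, at 7.58 ± 0.44 in homozygotes and 9.28 ± 0.90 in heterozygotes (SD, n = 3 each). An exact permutation test, two-sided, gave p = 0.1, the smallest that 3 against 3 allows. All homozygous arrays (7.15 to 8.03) lay below all heterozygous ones (8.27 to 10.01). This technical measure ran with genotype, and whether it bears on the differences between genotypes was not tested.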
